A study of Escherichia coli with 12 samples.

How the data were processed

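Purified 30S ribosomal subunits of 2 *Escherichia coli* strains, CK07 and CK09, were probed with dimethyl sulfate (DMS), which methylates the Watson-Crick face of unpaired A and C bases. Per the labels' protocols, ribosomes were treated for 4 min with 100 mM DMS and the reaction was quenched. The rRNA was then fragmented with zinc, size-selected, ligated to a linker and reverse transcribed with TGIRT-III, a reverse transcriptase that can read through methylated bases and leave a mutation. The cDNA was circularised and amplified by PCR, and the labels name no molecular identifiers, so reads are not known to be independent molecules. Errors computed from counts alone cover counting error only, while standard errors of the fits also hold the spread between libraries.

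The samples were grouped by strain and treatment as their titles give them: 4 DMS libraries and 2 libraries without DMS for each strain, 12 in all. The labels do not say that libraries of a group came from separate cultures or preparations, so p-values measure only the spread between these samples, which may be technical. The genotype label is Δ7prrn-BBB for both strains, whereas the column headers of the deposited tables pair CK07 with BBB and CK09 with HBB. This disagreement was not resolved, and the strains are named CK07 and CK09 throughout.

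The authors deposited a table of counts, per the file headers by 16S rRNA position and library, and these values are whole numbers of mutated reads. They also deposited a table with the mutation fraction for the same positions and libraries. Per the submitters' processing notes, cutadapt and Bowtie2 were used; their versions, their settings and the rules by which a mutation was counted are not given in the sources used here. Every deposited count divided by its fraction was whole to within 3.17e-06 reads, so that quotient was used as the read coverage of the position. It is unknown where the count was 0. Positions are given in the numbering of the deposited tables, and no genome build was named or used. The tables used here list A and C positions, 386 and 350 of them, with the same base in both strains at all 736; G and U positions were not analysed here, so the control on G and U that had been planned could not be made.

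Mutation counts were tested per position with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with log coverage as the offset. Positions needed a coverage of at least 1000 reads in every compared library and at least 20 mutated reads over them. P-values were adjusted by the Benjamini-Hochberg method and called at an adjusted p under 0.05. For the effect of DMS, all 12 libraries entered 1 fit with no further scaling. For the strain difference with DMS, the 8 DMS libraries were fitted alone, and the offset also held a scale per library, the median over positions of its mutation rate against the geometric mean of the compared libraries. The strain difference without DMS used the 4 libraries without DMS and no scale. The strain by DMS interaction used all 12 libraries, with scales set within the DMS and within the untreated libraries. Log2 fold changes are CK09 over CK07 unless stated. Standard errors (SE) were derived from the fold change and its F statistic. A count model with coverage as its offset does not hold the upper limit of a fraction and overstates the counting error at positions such as A915, where most reads were mutated.

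Library means of the mutation percentage were compared by an exact two-sided permutation test of 4 against 4, whose smallest possible p is 0.0286 (70 assignments of the labels). Region sets were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, over 26 regions with at least 5 tested positions. The regions and lists were helices, domains, natively modified bases and functional sites, with boundaries taken from textbook knowledge of the 16S rRNA secondary structure. They were fixed, with the tests, the rule for named positions and most of the other settings tried, before the data were examined.

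Named positions were, for the strain difference with DMS, up to 12 of the largest fold changes in each direction among called positions whose scaled rates did not overlap between strains, all called positions of helix 33, and all measured members of the modified and functional lists. For DMS itself they were the 10 highest mean fractions per strain. For untreated libraries the rule took differences in mean fraction of 0.5 or more, of which there were 0, and for the interaction up to 5 calls in each direction.

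The alternatives were other coverage and read minimums, other scales, DESeq2 1.42.0, limma on log2 rates with pseudocounts of 0.0001 or 0.001, limma on the deposited fractions, subtraction of the untreated fraction, the replicate number as a block, removal of the ends, and each library left out in turn. Chosen after seeing the data were a scale from positions that rose with DMS in both strains, a test of those positions alone, helix 33 left out, both replicate 4 libraries left out, and the subtraction with the smaller pseudocount.

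The test scripts were tested on simulated counts for 724 positions drawn from the real CK07 rates and the real coverages. Noise was drawn independently per position, with no shift shared within a library and about as many changes up as down. The real DMS libraries had scales from 0.905 to 1.10 and mostly lower calls, so the shares below may not hold for them. With DMS, 31.3% of strain differences of 1.2-fold, 98.5% of 1.5-fold and 100% of 2-fold were recovered, and 6.13% of calls were false. Without DMS, 22.4%, 62.7% and 92.4% were recovered at these folds, and for the interaction 1.49%, 43.3% and 83.3%. Of simulated 2-fold effects of DMS in CK07, 99.5% were recovered.

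Median coverage per position ran from 194916 to 245526 reads over the 12 libraries. In no group did a pair of libraries agree within counting error: the chi-square per degree of freedom was 1.16 and 1.25 for the untreated pairs and 2.25 to 84.6 for pairs of DMS libraries. No library was therefore counted as a duplicate. Positions A1518 and A1519 were blank in every library, and 4 positions at the ends held 0 in every library; these were not tested. Figures were drawn with matplotlib 3.10.9.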

Results

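DMS reactivity along the 16S rRNA of 30S subunits was measured in 2 *E. coli* strains with and without DMS. Each strain had 4 DMS libraries and 2 untreated libraries. Mutated reads over all listed positions totalled 1066980 to 1591220 per DMS library and 104676 to 112809 per untreated library. Median coverage per position was 194916 to 245526 reads. The listed positions were 386 A and 350 C between positions 1 and 1542.

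DMS raised the mutation rate at most A positions and at a minority of C positions. In CK07, 445 of 724 tested positions changed with DMS, 436 higher and 9 lower; in CK09, 438 changed, 436 higher and 2 lower (edgeR, adjusted p under 0.05). The rise was called in both strains at 419 positions, which were 332 of 379 tested A (87.6%) and 87 of 345 tested C (25.2%). No position fell in both strains; those lower in CK09 were C215 and C1263, named here after their values were seen. At an unadjusted p under 0.05 there were 455 positions in CK07 and 448 in CK09, and DESeq2 called 419 and 425. DESeq2 called 1 position lower in CK07 and 0 in CK09, so C215 and C1263 were not called lower by it.

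The most reactive position in both strains was A915, at the start of the 3′ major domain. It was mutated in 57.9% ± 3.85 (SD, n = 4) of reads in CK07 and 56.1% ± 5.01 (SD, n = 4) in CK09, against 0.0278% and 0.0333% without DMS. A1261 in helix 41 followed with 30.3% ± 2.49 and 29.6% ± 3.19 (SD, n = 4 each), then A432 in helix 16 with 29.1% ± 2.30 and 27.7% ± 3.06. A759 reached 19.3% and 18.7%, A560 17.7% and 17.2%, and A415 17.4% and 16.6% in CK07 and CK09. The set of the 10 highest positions was the same in both strains and was completed by A665, A190, A1201 and A782, with 12.1% to 15.7%. None of these 10 was called between strains; their log2 fold changes with DMS lay between -0.06 and 0.01.

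Overall modification was compared between strains from the mean over positions in each library. Mean mutation of A with DMS was 1.26% ± 0.127 (SD, n = 4) in CK07 and 1.22% ± 0.143 (SD, n = 4) in CK09, an exact permutation p of 0.6. Mean mutation of C was 0.369% ± 0.0275 and 0.359% ± 0.0313 (SD, n = 4 each), exact permutation p of 0.657. The Benjamini-Hochberg adjusted value was 0.657 for both bases. Without DMS the means were 0.0345% and 0.0341% for A and 0.0816% and 0.0804% for C in CK07 and CK09 (n = 2 each). The differences were within the spread between replicates, and their sign turned without CK09 DMS replicate 4, to 0.0209 percentage points for A and 0.00347 for C.

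The main comparison asked where the mutation rate with DMS differed between the strains. Of the 34 called positions, 26 were in the 3′ major domain, which forms the head of the subunit, 4 higher and 22 lower in CK09. Of those 26, 9 were not among the positions that rose with DMS in both strains, and 9 of the 34 also differed without DMS. With the untreated fraction subtracted, 6 positions were called at a pseudocount of 0.001 (1 higher, 5 lower) and 23 at 0.0001 (11 higher, 12 lower), of which 7 were shared with the 34. The central domain held 7 called positions, all lower, and the 5′ domain 1, while no position of the 3′ minor domain was called (0 of 66, with 1 at an unadjusted p under 0.05 and 0 by DESeq2). Helix 33, the beak of the head, held 11 of the 34. Over all 730 tested positions, 4 were higher and 30 lower in CK09 (edgeR, adjusted p under 0.05), with 86 at an unadjusted p under 0.05. The split of higher against lower calls depended on the scale: 1 and 11 with no scale, 8 and 22 with the mean rate, 11 and 18 with TMM, and 9 and 20 with a scale from positions that rose with DMS. Of the 34 calls, 12 were shared with no scale, 24 with the mean rate, 22 with TMM and 22 with the last of these.

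**Figure D1:**
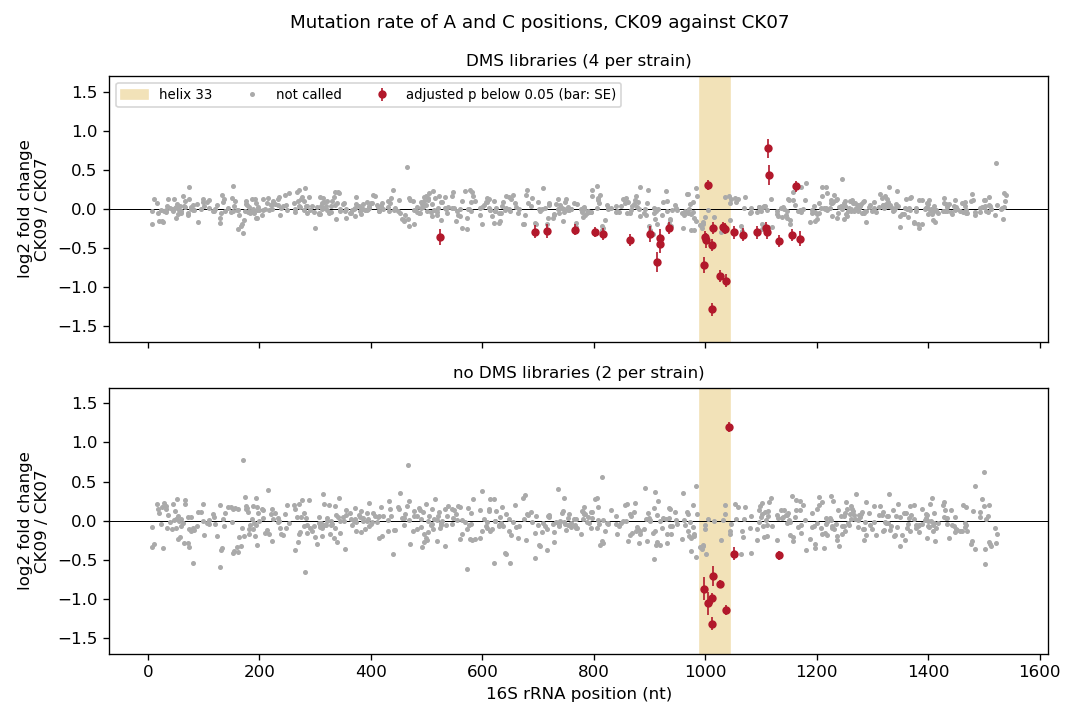
Log2 fold change of the mutation rate, CK09 over CK07, against 16S rRNA position in nucleotides, with DMS (top, 4 libraries per strain) and without (bottom, 2 per strain); red points passed an adjusted p of 0.05 with SE bars, grey points did not, and helix 33 is shaded. With DMS, 11 of 34 called positions lay in helix 33, and without DMS 8 of 10 did.

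In helix 33 (positions 991 to 1045), 10 of 22 tested positions were lower in CK09 and 1 was higher; 16 passed when adjusted over the list alone. C1011 fell from 0.0995% ± 0.00744 to 0.0396% ± 0.00218 (SD, n = 4 each), a log2 fold change of -1.28 ± 0.09 (SE). C1037 changed by -0.92 ± 0.08 (SE), C1027 by -0.85 ± 0.07, C998 by -0.72 ± 0.10 and C1001 by -0.40 ± 0.10 on the log2 scale. The edgeR adjusted p was 1.09e-20 for C1011, 1.33e-14 for C1037, 1.31e-15 for C1027, 3.42e-08 for C998 and 0.00599 for C1001. C1001 lost its call in 5 of 27 alternative settings, and its sign turned in 1 more. These 5 cytosines were not among the positions that rose with DMS in both strains, and their percentages with and without DMS were close: C1027 had 0.198% with and 0.190% without DMS in CK07, and 0.106% and 0.108% in CK09.

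The other called positions of helix 33 rose with DMS in both strains. A1004 was the highest of them, at 5.84% ± 0.895 in CK07 and 7.03% ± 1.18 in CK09 (SD, n = 4 each), a log2 fold change of 0.31 ± 0.06 (SE; edgeR adjusted p = 3.77e-04), although single libraries of the strains overlapped. C1031 was lower in CK09, with 2.40% ± 0.237 in CK07 and 2.00% ± 0.271 in CK09 (SD, n = 4 each; log2 fold change -0.23 ± 0.06, edgeR adjusted p = 0.00839). A1012 changed by -0.47 ± 0.08 (SE), A1000 by -0.36 ± 0.08, A1036 by -0.25 ± 0.07 and A1014 by -0.25 ± 0.07 on the log2 scale. The call was lost at A1014 in 13 of 28 alternative settings, at A1036 in 7, at A1004 in 6 and at C1031 in 5, with the sign kept. With no scale the adjusted p was 0.675 at A1004 and 0.514 at C1031 (edgeR). A1012 turned to 0.04 with the untreated fraction subtracted.

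**Figure D2:**
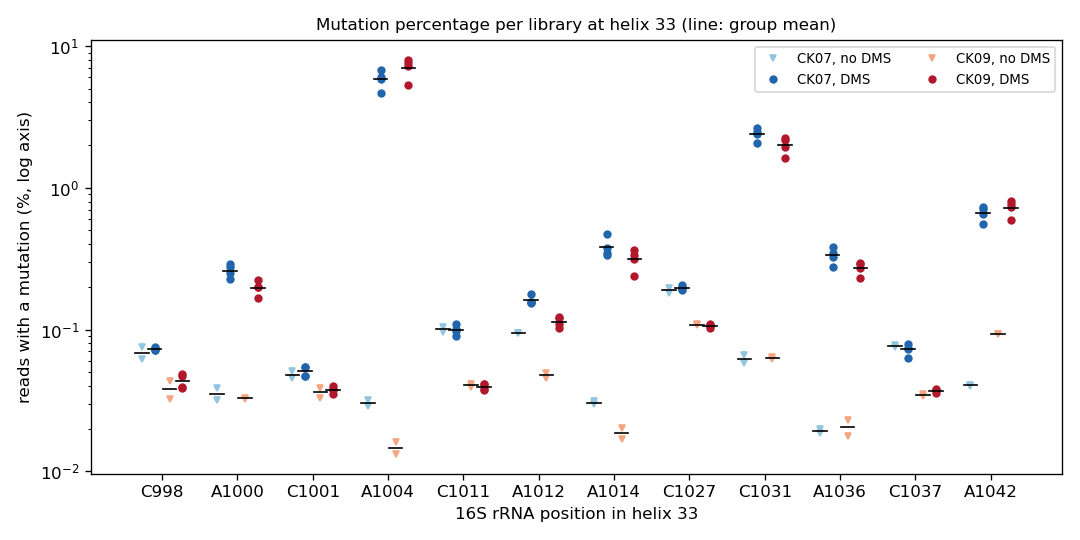
Percentage of reads with a mutation (log axis) at the 11 positions of helix 33 called with DMS and at A1042; each point is 1 library (triangles without DMS, circles with DMS; blue CK07, red CK09) and lines are group means. At C998, C1001, C1011, C1027 and C1037 the strains differed by about as much without DMS as with it, while C1031 had 0.0623% and 0.0628% without DMS.

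As a region, helix 33 had a mean log2 fold change of -0.29 and was the only 1 of 26 regions that camera called (limma adjusted p = 5.67e-11; adjusted p = 0.0440 with an estimated correlation). With the untreated fraction subtracted, the mean was -0.01 (camera adjusted p = 0.521). Another fit held only the 419 positions that rose with DMS in both strains and took its scale from them. There the mean over the 15 members of helix 33 was -0.09 (camera adjusted p = 0.105 over 24 regions). The scale and the positions compared changed along with the members. Fry, which asks whether the members of a region move 1 way, called helix 33 (adjusted p = 6.27e-04), the 3′ major domain (0.00305), helix 39 (0.0252) and helix 27 (0.0391), all lower in CK09. Camera with an estimated correlation did not call the 3′ major domain (adjusted p = 0.135), helix 39 (adjusted p = 0.205) or helix 27 (adjusted p = 0.255). The counts of called positions were 2 of 17 in helix 39 and 1 of 14 in helix 27.

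Outside helix 33, the highest rise in CK09 was at C1113, from 0.0335% ± 0.00410 to 0.0559% ± 0.00880 (SD, n = 4 each; log2 fold change 0.78 ± 0.12, SE; edgeR adjusted p = 1.85e-06). The untreated percentages of C1113 were 0.0318% and 0.0332%. A1163 rose from 0.452% ± 0.0589 to 0.538% ± 0.0448 (SD, n = 4 each; log2 fold change 0.29 ± 0.07), and C1114, named after its values were seen, had a log2 fold change of 0.44 ± 0.13. A914, beside the most reactive base A915, was lower in CK09 by -0.68 ± 0.13 (SE; edgeR adjusted p = 1.13e-04), at 0.0716% ± 0.00843 against 0.0439% ± 0.00436 (SD, n = 4 each). A864 in helix 26 changed by -0.40 ± 0.08, A1169 by -0.38 ± 0.10 and A919 by -0.38 ± 0.12. The call was lost at A919 in 18 of 29 alternative settings, at A1169 in 7 and at A1163 in 6, each time with the same sign; with no scale the adjusted p at A1163 was 0.464 (edgeR). C1132 in helix 39 changed by -0.41 ± 0.08, with -0.44 between the untreated libraries.

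Of the 34 called positions, 25 rose with DMS in both strains (2 higher and 23 lower in CK09) and 9 did not. The scaled rates of the 4 CK07 and 4 CK09 libraries did not overlap at 27 of the 34; over all tested positions this was so for 57 of 730 (7.81%), where chance gives 2.86%. With the untreated fraction subtracted and a pseudocount of 0.001, 6 positions remained called: C1113 higher, and A802, C817, C934, A1000 and A1155 lower in CK09. Of these, A802, C817, C934 and A1155 were named after their values were seen.

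A list of 11 A and C positions at the decoding centre, the P site and the bridges to the large subunit was fixed in advance. None of the 11 was called, over all positions or adjusted over the list alone, and their log2 fold changes lay between -0.07 and 0.07. DESeq2 also called 0 of them, and 0 had an unadjusted p under 0.05 in edgeR. A1408 in the decoding site had 5.42% ± 0.607 in CK07 and 5.13% ± 0.588 in CK09 (SD, n = 4 each). A1492 had 2.11% ± 0.216 and 2.00% ± 0.253, and A1493 had 1.80% ± 0.237 and 1.77% ± 0.165. A532 in helix 18 had 5.63% and 5.51%, A702 in helix 23 had 4.24% and 4.12%, and A790 in helix 24 had 3.78% and 3.61%. Over the wider set of bridge positions, 1 of 19 was called, A900 in helix 27 (log2 fold change -0.32 ± 0.10, SE; edgeR adjusted p = 0.0439), named after its values were seen. Its call was lost with the scale from DMS-responsive positions (edgeR adjusted p = 0.126) and without both replicate 4 libraries (0.124).

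Among natively modified bases, 5 of the 11 list members were listed and 3 could be tested. C967, a methylated cytosine of helix 31, had 1.35% ± 0.168 in CK07 and 1.496% ± 0.120 in CK09 (SD, n = 4 each), a log2 fold change of 0.19 ± 0.06 (SE). It was not called over all positions (edgeR adjusted p = 0.0749) and was the 1 call adjusted over the list alone; it was called over all positions in 10 of 29 alternative settings. Among these were DESeq2 (adjusted p = 0.0284) and the scales from the mean rate (0.00349), TMM (0.00837) and DMS-responsive positions (9.41e-04). Another was the replicate number as a block (edgeR adjusted p = 1.75e-05). C1402, which carries methyl groups on base and sugar, had 1.18% and 1.11% without DMS in CK07 and CK09, and 1.55% ± 0.118 and 1.64% ± 0.0354 with DMS (SD, n = 4 each). C1407 had 0.435% and 0.405% with DMS.

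Without DMS, the strains differed at 10 of 723 positions, 1 higher and 9 lower in CK09 (edgeR, adjusted p under 0.05; 49 at an unadjusted p under 0.05), and 8 of the 10 lay in helix 33. A1042 was higher in CK09, 0.0403% against 0.0929% (n = 2 each), a log2 fold change of 1.204. C1011 changed by -1.32, C1037 by -1.14, A1004 by -1.06, A1012 by -0.99, C998 by -0.87, C1027 by -0.81 and A1014 by -0.71. The others were C1051 in helix 34 and C1132. These positions were named after their values were seen, since no untreated difference reached 0.5 in mean fraction. Leaving out either CK07 untreated library left 5 calls.

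The strain by DMS interaction, which tests whether the fold change with DMS differed, was called at 2 of 724 positions. At A1004 the rise with DMS was larger in CK09 by 1.34 ± 0.20 (SE) on the log2 scale (edgeR adjusted p = 8.54e-06). This call was lost with no scale (1.32, edgeR adjusted p = 0.161) and with limma at a pseudocount of 0.001 (0.48, adjusted p = 0.195). The untreated percentage of A1004 was 0.0304% in CK07 and 0.0146% in CK09. At A1042 the interaction was -1.06 ± 0.13 (SE; edgeR adjusted p = 8.74e-08); with DMS it had 0.662% and 0.724%, a log2 fold change of 0.17 that was not called (edgeR adjusted p = 0.140). This strain difference with DMS was called in 7 of 28 alternative settings. Among them were the scales from the mean rate (edgeR adjusted p = 0.00260), TMM (0.0209) and DMS-responsive positions (0.00140). Another was the replicate number as a block (edgeR adjusted p = 5.43e-05). A1042 also lost its interaction call with limma at 0.001 (-0.32, adjusted p = 0.161). At an unadjusted p under 0.05 there were 34 positions.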

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

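Of the tests in this part, the mean of helix 33 over other splits was fixed before its result was seen; all other tests of explanations, and the coverage comparison, were chosen only after the results were seen.

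At A1004 and A1042 the fold change with DMS differed between strains by an interaction test, with log2 values of 1.34 and -1.06. The rise in percentage points was 5.81 in CK07 and 7.01 in CK09 at A1004, but about the same at A1042, 0.622 and 0.631. At both positions the untreated rate differed by a larger factor than the rate with DMS. In 11 of 94 groups of 4 libraries, 1 library stood far from the other 3. The cutoff is meant to pass about 1 in 20 independent groups, but these groups share the same 8 libraries, so the count does not test chance. Of the 11, 9 were in a replicate 4 library of either strain. With scaled percentages, CK07 replicate 4 was low at A864 (0.106), C1031 (2.24), A702 (3.88), A759 (17.9) and A190 (12.7). CK09 replicate 4 was low at C1113 (0.0477) and A759 (17.4) and high at C1037 (0.0418) and C1027 (0.121). CK07 replicate 1 was high at C1113 (0.0357), and CK09 replicate 1 was high at C967 (1.56).

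The first pattern was the lower rate of C998, C1001, C1011, C1027 and C1037 in CK09. The median of their log2 fold change with DMS minus that without was 0.0318, so the difference is present without DMS and need not involve it. CK09 coverage was up to 1.02 higher on the log2 scale at 21 positions between 1011 and 1534, against a median of 0.05 elsewhere. Elsewhere it was up to 0.45 higher at single positions and lower at others. Among the latter were C1113 (-0.28 with DMS and -0.46 without) and C1132 (-0.24 and -0.33). Whether the lower coverage bears on the calls at C1113 and C1132 was not tested. Dilution by extra unmutated reads would lower all covered positions alike. Over 17 untreated positions between 1011 and 1055 with a coverage gain of 0.5 or more, the fold change plus the gain had a median of 0.73 (quartiles 0.20 and 0.94), not 0. Still, untreated C1027 changed by -0.81 with a gain of 1.00 and C1037 by -1.14 with 0.93. C1011 changed by -1.32 with a gain of 0.73, and C1001, not called without DMS, by -0.42 with 0.13. C998 changed by -0.87 with about the same coverage in both strains. A sequence difference between the strains beside these bases, or how reads were aligned across it, may account for both the coverage and the background and was not tested.

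In the second pattern, helix 33 positions that rose with DMS differed between strains. A1000, C1031 and A1036 were not called without DMS. With the untreated level subtracted, 3 of 3 kept the sign and at least 0.5 of their log2 fold change, without overlap between strains. They were picked for not being called without DMS, so this result was largely set by the choice and does not test background. A1004 was lower without DMS (-1.06) but higher with it. Untreated C1031 had 0.0623% in CK07 and 0.0628% in CK09, against 2.40% and 2.00% with DMS. Untreated A1004 had 0.0304% and 0.0146%, against 5.84% and 7.03%. Background of this size is too small to make up the strain difference at C1031 or A1004. Of these 4, only A1000 stayed called in limma with subtraction (adjusted p = 0.0310). Limma gave C1031 -0.22 ± 0.05 (SE) before and -0.23 ± 0.06 after (adjusted p = 0.121), and A1036 -0.19 ± 0.04 and -0.19 ± 0.06 (0.165). A1004, not called by this limma fit before either, had 0.30 ± 0.08 and 0.31 ± 0.08 (0.106). At C1031 and A1036 the fold was kept and the SE rose. Calls over all positions also fell from 28 to 6 with subtraction, which itself moves adjusted p-values. Why the calls at C1031 and A1036 ended was not tested. At A1012, A1014 and A1042 the untreated rates differed in the direction seen with DMS, and 1 of 3 (A1014) had as much of its fold change after subtraction. A1012 then had 0.0635% in CK07 and 0.0669% in CK09 (scaled), so its lower rate with DMS went with the background. A1042 had 0.608% and 0.636%, and limma did not call it before (adjusted p = 0.212) or after (0.923). A1014 overlapped between libraries after subtraction. Limma did not call it before (-0.19 ± 0.07, SE, adjusted p = 0.212) or after (-0.15, adjusted p = 0.486). After subtraction A1014 had 0.343% in CK07 and 0.297% in CK09 (scaled), a log2 ratio of -0.21 against a fold change of -0.25. The untreated level thus made up a minor part of the gap between its means. Its libraries overlapped before subtraction as well, so whether A1014 differs between strains with DMS stays open. Over 9 helix 33 positions that rose with DMS and had a coverage gain of 0.5 or more, the fold change plus the gain had a median of 0.77 (quartiles 0.65 and 0.96), not 0, which argues against dilution, and a local difference in structure stays open, untested.

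The third pattern was the lower rate in CK09 of 18 positions outside helix 33 that rose with DMS. A uniform lower modification left by the scaling would move all positions that rose with DMS alike. Over all 419 of them the median was -0.0213 (quartiles -0.08 and 0.03), so a uniform shift left after scaling was about that size. The scale, a median over all tested positions, itself holds this value near 0. The 18 were picked as lower, so their median of -0.32 lies below that of the 419 by choice and is no test. A shift that depends on how reactive a position is was not tested. Under a scale from DMS-responsive positions, 10 of the 18 stayed called and 8 did not (adjusted p 0.0838 to 0.174); the median of the 8 went from -0.34 to -0.31, with a median SE of 0.10 before and after, and why their calls ended was not tested. Leaving out both replicate 4 libraries, the least modified ones, left 16 of 18 called, so those 16 calls did not rest on these libraries. The other libraries had also served to pick the 18. The coverage gain at the 18 ran from -0.28 to 0.16 (median 0.07), and their fold changes from -0.68 to -0.25. The fold change plus the gain had a median of -0.26, but this was largely set by picking lower positions and does not test coverage. A strain difference in structure stays open as a hypothesis, as does any unrecorded difference between preparations.

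Other splits of the 8 DMS libraries into 4 and 4 were refitted, 35 in all. The real split called 34 positions and the highest other split 1, so 1 of 35 splits, the real one, reached that count. This is the smallest share the test can give, which argues against chance but does not exclude it. Splits cannot tell a strain difference from an unrecorded difference between preparations. For the number of called regions, 16 of 35 splits reached the real count of 1, with 4 as the highest other, so chance is not excluded for that count. The mean of helix 33, 0.29 in size, was reached by 1 of 35 splits, the real one, with 0.18 as the highest other. That is again the smallest share possible and argues against chance without excluding it.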

How the results depend on the processing

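Alternatives added after seeing the data were the scale and the test from DMS-responsive positions, helix 33 left out, both replicate 4 libraries left out, and the subtraction with a pseudocount of 0.0001. The strain difference with DMS (34 positions) gave 12 with no scale, 19 with limma at a pseudocount of 0.0001, 9 with limma on the deposited fractions, 6 with the untreated fraction subtracted and 17 with helix 33 left out. With the subtraction at the smaller pseudocount it gave 23, of which 7 were shared with the 34. Without DMS (10 positions), limma gave 5 and 6 at pseudocounts of 0.0001 and 0.001. The interaction (2 positions) gave 1 with no scale, which lost A1004, and 0 with limma at 0.001. Region sets (1 region) gave 4 with fry and 0 with either subtraction, with DMS-responsive positions only and with helix 33 left out. The signs turned with the untreated fraction subtracted at C1011 (0.0189), C1037 (0.0686), C998 (0.0486), A1012 (0.0377) and C1001 (0.0223), and at the smaller pseudocount at C1037 (0.289), C998 (0.0511) and A1012 (0.0353). Subtraction removes the difference that these positions have without DMS; the cause of the other shifts was not tested. Replicate numbers were not taken to pair the libraries, since not every pair correlated over 0.1 and no label says that a number marks a shared batch. Same-number correlations were 0.229, 0.175, 0.0175 and 0.391. CK07 replicates 1, 2 and 4 but not 3 correlated best with their own number, so a pairing by number stays open. With the number as a replicate block, 76 positions were called, including all 34, and C967, A1042 and C1402 were gained among named positions. With single libraries left out, the strain difference with DMS ran from 23 (without CK09 replicate 2) to 43 (without CK07 replicate 4), without DMS from 5 to 11, the interaction from 2 to 3, DMS in CK07 from 416 to 446 and in CK09 from 418 to 440, regions from 1 to 1, and the strain difference in mean mutation from -0.102 to 0.0209 percentage points for A and -0.0219 to 0.00347 for C. A lone untreated library was assumed to vary like the other groups. Both replicate 4 libraries left out gave 48, with 32 shared. The background limits and the minimum of 100 reads removed no tested position, so those settings show nothing. With no minimum of mutated reads the strain difference with DMS was also the same 34 of 730. These settings are still counted among the alternatives given for each named position, so those counts overstate how many settings could change a call. Leaving out positions near a sequence difference could not be run because no position met its condition. All 736 listed positions had the same base in both strains, so this does not show that the 2 sequences are alike.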

Other observations

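Of the tests here, the context test was fixed before its result was seen, and the enrichment test was chosen after.

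Positions that differed without DMS were concentrated in helix 33: 8 of 22 tested there against 2 of 701 elsewhere (Fisher's exact test, two-sided p = 7.80e-12). With DMS the counts were 11 of 22 and 23 of 708 (Fisher's exact test, two-sided p = 1.99e-10). Neighbouring positions share reads and are not independent, so these p-values are too small. The 3′ minor domain, with 66 tested positions and the long helix 44 that holds the decoding site, had 0 calls, with a mean log2 fold change of 0.03. Its single positions ran from -0.17 to 0.59, so 0 calls does not show that every position was alike.

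At C1113 the change with DMS was 0.08 ± 0.16 (SE) on the log2 scale in CK07 (edgeR adjusted p = 0.759) and 0.75 ± 0.17 in CK09 (edgeR adjusted p = 7.58e-04). The interaction at C1113, 0.70 ± 0.21 (SE), was not called on the log2 scale (edgeR adjusted p = 0.267), while the level with the untreated fraction subtracted was called between strains (0.30, limma adjusted p = 0.0163). Untreated C positions had a higher mean mutation percentage than A positions, 0.0816% against 0.0345% in CK07.

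A hypothesis that the background of C depends on the next base was tested by setting 182 C followed by an unlisted base against 167 followed by a listed A or C. The ratio of medians was 1.04 (0.0507% and 0.0488%; permutation p = 0.641), which argues against a difference of 1.5-fold or more from this property.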
